A study of Homo sapiens with 2 samples.

How the data were processed

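RNA was sequenced from HepG2, a human liver cancer cell line, carrying a cassette from which doxycycline (Dox) switches on SAMD4B. SAMD4B is a human homologue of the fly RNA-binding protein Smaug. The series holds 2 libraries, 1 grown without Dox and 1 grown with 1 µg/ml Dox, with 48 h of culture stated for both. RNA was extracted with a column kit and the molecule is given as polyadenylated RNA, per the labels. There is 1 library per group, so no spread between replicates can be had, no p-value is given, and every difference is a difference between these 2 libraries. No library of cells given Dox without the cassette was analysed here, so an effect of Dox itself cannot be separated from an effect of SAMD4B.

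The authors deposited TPM values, transcript abundances corrected for length and scaled to a fixed total within each library, for 184844 Ensembl transcripts in 1 table. Per the submitters' processing notes, Trimmomatic, Salmon and the genome build GRCh38.p13 were used. Their versions, options and annotation release are not given in the sources used here. Each column summed to 1000000. Salmon shares fragments among transcripts that match them equally well, so the TPM of a single transcript, or of a gene with near-identical copies, can move between copies without any change in the cells. TPM also divides by transcript length, so a gene's summed TPM moves when fragments are moved between its long and short transcripts.

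Transcripts were named through GENCODE release 29 (GRCh38) by Ensembl identifier without version. Of the 184844 transcripts, 161798 matched, and they held 93.3% of the TPM in each library. The 23046 others, with 6.73% of the TPM without Dox and 6.66% with Dox, are newer or lie outside the primary assembly used here, and could not be given a gene. A gene's value is the sum of the TPM of its matched transcripts, so fragments assigned to an unmatched transcript of the same gene are missed. Genes of the fixed lists that had no matched transcript were not analysed here. Current symbols came from a table of gene identifiers. Where several identifiers carried the same symbol, the most abundant was kept (18 dropped). Biotypes and coordinates are those of GENCODE release 29.

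Fold changes are log2((TPM with Dox + 1)/(TPM without Dox + 1)), which understates the change of genes with low values. Genes with a mean TPM of at least 1 over both libraries were compared (11582 genes, 11112 of them protein-coding), and a fold of 2 in either direction was counted. Named genes were chosen by a rule set before the data were examined. They are SAMD4B, its paralogue SAMD4A, the 13 protein-coding genes with the largest and the 13 with the smallest log2 fold change at a mean TPM of at least 5, up to 4 members of each gene list that stood apart and up to 2 members of each other list. Some genes that this rule takes are not reported here. Any other gene named, such as a member that went against its list's median, was chosen after its values were seen. A total of 35 gene lists was fixed before the data were examined. For each list with at least 5 members at a mean TPM of at least 1 (34 lists), the median log2 fold change was ranked among 10000 random lists of the same size, drawn from 20 bins of mean TPM. A list was said to stand apart below percentile 2.5 or above 97.5. Members of a list are often regulated together and random genes are not, so these percentiles describe the 2 libraries and are not tests of the treatment. Members at least 1.5-fold higher or lower were counted beside each median.

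TPM tables state no depth, but the low values showed steps. For single-transcript genes of at least 600 nt, TPM multiplied by the length less an offset of 300 nt (without Dox) or 310 nt (with Dox) fell near whole multiples of one value in each library. Of the values worth under 5.5 fragments, 85.1% (383 of 450) without Dox and 86.2% (401 of 465) with Dox lay within 0.1 of a whole number. With a value and an offset fixed beforehand, 20% would by chance. Both were fitted to these same low values, so the shares are no independent check of the estimate. By this estimate the libraries held 18354994 and 23810075 fragments on matched transcripts of at least 600 nt, and the library with Dox was 1.30 times as deep. A transcript of 2000 nt with 1 fragment has a TPM of about 0.0396 without Dox and 0.0314 with Dox. Ratios of estimated fragments, each divided by its library's estimated depth, are given with exact 95% binomial intervals (Clopper-Pearson) for genes with at least 80% of their TPM on transcripts of at least 600 nt. These intervals rest on the estimated depth and cover counting error only. They cover neither biological variation nor the sharing of fragments among transcripts.

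The procedure was tested on simulated data, with fragments drawn at the estimated depths for the real transcripts. In 100 simulated pairs of libraries without any change, counting error alone put a mean of 27.6 genes (highest 39) at least 2-fold higher and 23.2 genes (highest 37) at least 2-fold lower. A mean of 1.5 lists stood apart in the 10 pairs in which lists were ranked. Of 98 tested genes with a simulated 4-fold change in this comparison, 95 passed the 2-fold limit, as did 1 of 99 with a 1.5-fold change.

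The alternatives were pseudocounts of 0.1 and 5 TPM, 3 other scalings, no filter and a minimum mean TPM of 5, protein-coding genes alone, folds of 1.5 and 4, and random lists matched also on transcript length. After the data were seen, further alternatives were added. These were estimated fragments relative to depth in place of summed TPM (9786 genes, those that meet the same 80% rule), the removal of genes whose main transcript in one library is listed at 0 in the other, and random lists matched also on GC content. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.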

Results

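To learn which transcripts differ in HepG2 cells when SAMD4B is overexpressed, polyadenylated RNA was profiled in 1 library without Dox and 1 library with Dox. HepG2 is a human liver cancer line that still expresses many hepatocyte genes. The depths, estimated from the steps of the low values, were 18354994 fragments without Dox and 23810075 with Dox. TPM above 0 was listed for 66763 transcripts without Dox and for 70630 with Dox. Across the 11582 genes compared, the log2 of TPM plus 1 correlated between the libraries with a Pearson r of 0.98. This r was taken across genes, which are not independent replicates. On the scale of TPM plus 1, 90.8% of these genes differed by less than 1.5-fold. Transcripts of the mitochondrial genome held 10.2% of the TPM without Dox and 11.2% with Dox. MT-ATP8 alone was listed at 43419 TPM without Dox and 50987 with Dox. Its transcript of 207 nt is shorter than the length offsets, so its TPM, and with it much of this share and its rise, is uncertain. Retained-intron transcripts held 4.30% and 4.25%, and pseudogene transcripts 1.11% and 0.99%.

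SAMD4B (ENSG00000179134, chromosome 19, 39342396 to 39385710, GRCh38), the induced gene, was higher in the library with Dox, as its label states. Its summed TPM was 47.5 without Dox and 261 with Dox, a log2 fold change of 2.44. In estimated fragments relative to depth the ratio was 7.47, with a 95% counting interval of 6.99 to 7.99. The change lay in 3 of its transcripts. ENST00000598913 was at 1.42 TPM without Dox and 112 TPM with Dox, ENST00000596368 was listed at 0 and 86.4, and ENST00000610417 was at 13.7 and 36.6. The longest transcript listed, ENST00000314471 with 4519 nt, was at 2.58 TPM without Dox and 1.32 with Dox. Fragments of the cassette and of the resident gene cannot be told apart in these values. The paralogue SAMD4A was at 3.36 TPM without Dox and 4.44 with Dox (fragment ratio 1.11, interval 0.94 to 1.31).

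**Figure D1:**
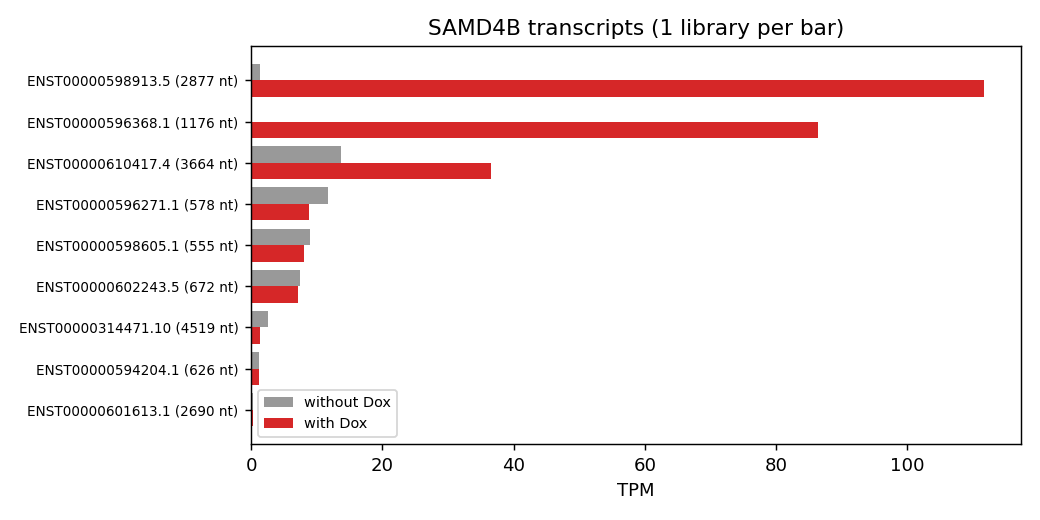
TPM (horizontal axis) of each SAMD4B transcript with a value above 0, with grey bars for the library without Dox and red bars for the library with Dox, 1 library per bar. ENST00000598913, ENST00000596368 and ENST00000610417 carry the higher value with Dox, and the other transcripts stay below 13 TPM in both libraries.

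Among the 13 largest values, ANKRD1, a nuclear ankyrin-repeat protein of muscle and stressed cells, was at 95.5 TPM without Dox and 606 with Dox (log2 fold change 2.65, fragment ratio 6.17, interval 5.91 to 6.44). CCN1, a matricellular protein, was at 5.51 and 35.0 TPM (2.47 on the log2 scale). F2RL1, the protease-activated receptor PAR2, was at 8.68 and 56.4 TPM (2.57). LOXL4, a lysyl oxidase that cross-links collagen, was at 0.65 and 14.6 TPM (3.24, fragment ratio 21.5, interval 15.2 to 31.5). The growth-responsive transcription factor EGR1 was at 2.99 and 16.5 TPM (2.14), and DKK1, a secreted Wnt antagonist, was at 1.70 and 10.9 TPM (2.14). S100A6, a calcium-binding protein, was at 3.32 and 16.8 TPM, the zinc-finger gene ZNF114 at 6.26 and 30.6 TPM, and the keratin-associated KRTAP3-1 at 4.34 and 27.9 TPM. In total 188 genes were at least 2-fold higher with Dox and 112 at least 2-fold lower. Counting error alone gave means of 27.6 and 23.2 in simulated pairs of libraries.

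The other 4 of the 13 largest differences were genes whose main transcript in one library was listed at 0 in the other. They were ENSG00000273590 (0.38 and 30.9 TPM), FLOT1 (listed at 0, then 19.7 TPM, on its only 1 matched transcript), BAG6 (1.28 and 20.6 TPM) and ERN1 (1.63 and 10.0 TPM), the IRE1 sensor of the unfolded protein response. Such all-or-none values made up 67 of the 188 higher and 64 of the 112 lower genes. Without them, 121 genes were at least 2-fold higher and 48 at least 2-fold lower.

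Among the 13 smallest values, RRM2, the small subunit of ribonucleotide reductase, was at 50.2 TPM without Dox and 20.1 with Dox (log2 fold change -1.28). Most of the RRM2 difference lay in ENST00000304567, at 28.8 and 3.84 TPM, and no fragment ratio with an interval was estimated for this gene. In fragments on its transcripts of at least 600 nt, which held 53.8% of its TPM, the log2 fold change was -2.29. NTHL1, a DNA glycosylase of base excision repair whose exons partly overlap TSC2 on the opposite strand, was at 14.5 and 1.34 TPM (-2.72). PIGW, an enzyme of glycosylphosphatidylinositol anchor synthesis, was at 9.22 and 1.27 TPM (-2.17), and the xylosyltransferase gene GXYLT2 at 15.7 and 4.65 TPM (-1.56), with 6.16 TPM of the former on ENST00000491839, which was listed at 0 with Dox. BOLA2B, which has a near-identical paralogue and is therefore uncertain, was at 25.3 and 6.24 TPM, and ENSG00000167774 at 8.20 and 2.40 TPM. A further 6 again had a main transcript listed at 0 in one library. GMPR2 (26.8 TPM) and PPP1R10 (15.6 TPM), each with only 1 matched transcript, were listed at 0 with Dox. ZBED1 (10.7 and 0.23 TPM), SMIM11 (39.4 and 3.85), SHMT1 (27.7 and 4.71) and FAM156A (9.71 and 1.49) kept a small value.

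**Figure D2:**
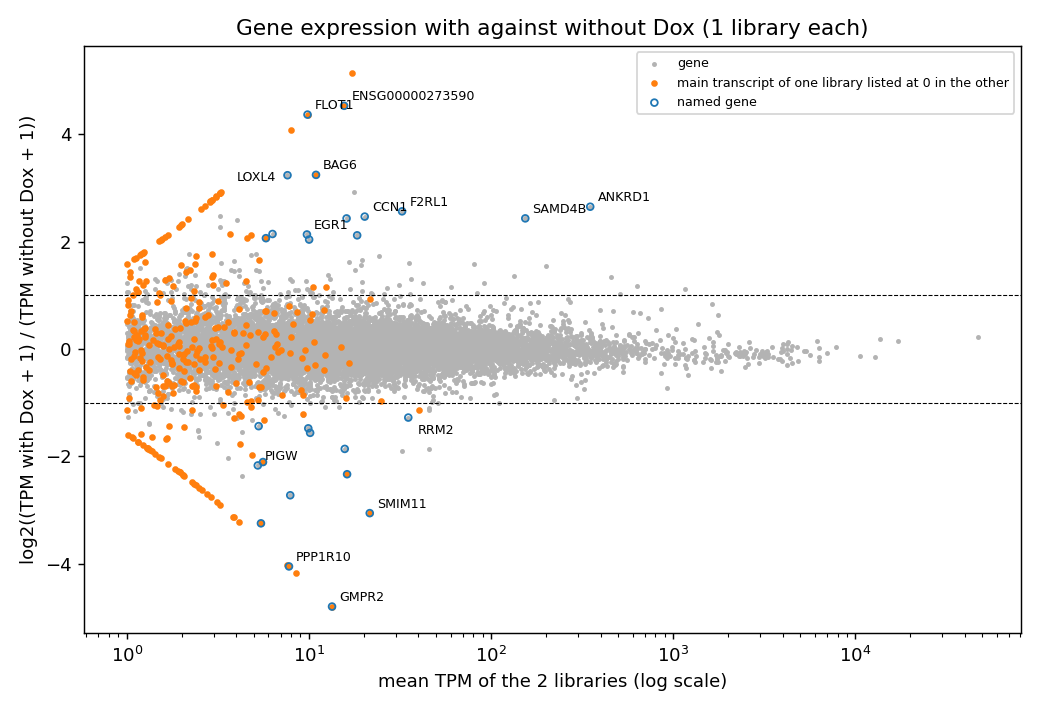
Log2 fold change with against without Dox (vertical axis, pseudocount of 1 TPM) against the mean TPM of the 2 libraries (horizontal axis, log scale), 1 point per gene, with dashed lines at 2-fold. Orange points are genes whose main transcript in one library is listed at 0 in the other, and they make up 131 of the genes beyond the dashed lines, while ANKRD1 and SAMD4B stand apart at high TPM.

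Of the 34 gene lists ranked, 15 stood apart from random lists, 8 with a higher and 7 with a lower median with Dox, where 1.7 would be expected by chance for independent genes. The list of AP-1 and immediate early genes, which respond to growth signals within minutes to hours, had the highest median. All of its 18 measured members were higher with Dox, 11 of them by at least 1.5-fold, and the median was 0.79 on the log2 scale. None of 10000 random lists reached this value. With a pseudocount of 5 TPM the median was 0.39, and the list still stood apart. EGR1 led the list. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, was at 54.4 TPM without Dox and 130 with Dox, the phosphatase gene DUSP4 at 2.24 and 6.61, and FOS at 0.60 and 2.74.

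The list of TGF-beta targets, epithelial-mesenchymal transition and matrix genes had a median of 0.51. Of its 16 measured members, 11 were higher, 7 of them by at least 1.5-fold, and none was lower by that much. None of the random lists reached its median. The members that led it included signal-responsive genes. CCN2, a matricellular protein like CCN1, was at 258 TPM without Dox and 659 with Dox (fragment ratio 2.48, interval 2.42 to 2.55). ID2, an inhibitor of basic helix-loop-helix factors, was at 181 and 347 TPM. The matrix protein FN1 and the cadherins CDH1 and CDH2, looked up after the values were seen, had log2 fold changes of -0.10, -0.39 and -0.13. This list did not stand apart when genes below a mean TPM of 1 were kept.

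Glycolysis and hypoxia genes were higher as a group, with 22 of 23 measured members above their value without Dox, 6 by at least 1.5-fold, and a median of 0.30. None of the random lists reached it. The glucose transporter SLC2A1 was at 1180 TPM without Dox and 2111 with Dox, and SLC2A3 at 386 and 879 TPM. PFKP, the platelet-type phosphofructokinase, was at 1.51 and 5.93 TPM, and the hexokinase gene HK1 at 7.24 and 15.6 TPM. Metallothioneins and metal-response genes had a median of 0.45, with 11 of 12 higher and 5 of them by at least 1.5-fold. MT2A was at 640 and 1074 TPM, MT1M at 22.3 and 37.2, MT1A at 39.4 and 72.9, and MT1B was listed at 0 without Dox and at 4.05 with Dox. These are near-identical genes, so the split of fragments among them is uncertain. The zinc and manganese transporter gene SLC30A10, looked up after the values were seen, was at 2.83 and 1.32 TPM. No fragment ratio could be estimated for MT1A or MT1B.

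Beta-catenin target genes had a median of 0.30, with 12 of 16 higher and 4 by at least 1.5-fold, and 2 of 10000 random lists reached it. AXIN2 was at 129 TPM without Dox and 209 with Dox, TBX3 at 77.7 and 122, and LGR5 at 68.8 and 106, beside DKK1. RHBG and GLUL, looked up after the values were seen, had log2 fold changes of -0.55 and -0.43. NRF2 targets had a median of 0.20, with 14 of 20 higher and 1 by at least 1.5-fold. GCLC, the catalytic subunit of glutathione synthesis, was at 77.1 and 129 TPM, and TXNRD1, ABCC2 and OSGIN1 had log2 fold changes of 0.53, 0.42 and 0.37. In estimated fragments the median of the NRF2 list was 0.11.

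Interferon-stimulated genes went both ways. Their median was 0.29, with 15 of 22 higher, 4 by at least 1.5-fold, and 1 lower by at least 1.5-fold, and 5 of 10000 random lists reached it. IFITM1, a membrane protein that restricts virus entry, was at 83.6 TPM without Dox and 152 with Dox, and IFITM2 at 47.1 and 73.3. IFI27 (1.68 and 4.24 TPM) and OAS1 (1.92 and 4.46) lay near the filter, and OAS1 had a log2 fold change of -0.01 in estimated fragments on its transcripts of at least 600 nt. STAT2 (12.7 and 8.78 TPM) and OAS3 (2.39 and 0.69 TPM), looked up after the values were seen, were lower with Dox. With a pseudocount of 5 TPM the median was 0.12 and the list did not stand apart.

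The acute phase list had a median of 0.28, with 7 of 10 higher, 1 higher by at least 1.5-fold and 2 lower by as much. SERPINA3 was at 120 TPM without Dox and 165 with Dox, IL6R at 11.3 and 16.1, and SOCS3 at 3.57 and 5.43. LCN2 was at 0.64 and 2.39 TPM, but its log2 fold change was -0.11 in estimated fragments on its transcripts of at least 600 nt. HP, the haemoglobin-binding plasma protein haptoglobin, looked up after the values were seen, was at 386 and 205 TPM, and IL1RN at 6.84 and 3.78 TPM. The list did not stand apart with a minimum mean TPM of 5.

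Cell-cycle genes were lower with Dox. All of the 27 genes of DNA replication and S phase were below their value without Dox, 3 of them by at least 1.5-fold, with a median of -0.42 that none of 10000 random lists reached. After RRM2, the flap endonuclease FEN1 had a log2 fold change of -0.74 (fragment ratio 0.57, interval 0.53 to 0.62), and the licensing factors CDC6 and CDT1 were at 58.9 and 35.2 TPM and at 12.7 and 8.42 TPM. Of the 27 genes of G2 and mitosis, 25 were lower, 3 by at least 1.5-fold, with a median of -0.24. BIRC5, which codes for survivin, was at 87.4 and 54.2 TPM, the kinase PLK1 at 111 and 70.9, the kinesin KIF20A at 37.7 and 24.3, and CCNA2 at 62.1 and 44.1.

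Genes of cholesterol synthesis and uptake were lower with Dox in 21 of 24 cases, 3 of them by at least 1.5-fold, with a median of -0.29 that none of the random lists reached. HMGCS1, an early enzyme of the mevalonate pathway, was at 292 TPM without Dox and 151 with Dox (fragment ratio 0.51, interval 0.50 to 0.52), MVD at 54.0 and 30.9 TPM, and HSD17B7 at 50.2 and 33.9 TPM. The list of fatty acid and triglyceride synthesis had a median of 0.00 and did not stand apart, although FASN, the fatty acid synthase, was at 82.5 and 46.8 TPM and DGAT2 at 23.1 and 13.4 TPM. The elongase gene ELOVL6, looked up after the values were seen, was at 19.1 and 32.9 TPM, but its log2 fold change was -0.11 in fragments on transcripts of at least 600 nt.

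Of the lists of hepatocyte genes, those of secreted plasma proteins and of bile acid genes stood apart as lower, while the acute phase list stood apart as higher. Of 23 secreted plasma proteins, 19 were lower, 1 of them by at least 1.5-fold, with a median of -0.20 that none of the random lists reached. The log2 fold changes were -0.62 for HPX, -0.45 for APOC3, -0.44 for APOH and -0.42 for VTN. Bile acid synthesis and transport genes were lower in 8 of 10 cases, 3 by at least 1.5-fold, with a median of -0.25. HSD3B7 was at 23.9 TPM without Dox and 13.4 with Dox, SLC27A5 at 27.5 and 17.8, CYP27A1 at 100 and 72.2, and the transporter subunit SLC51A at 2.45 and 0.92. The SLC51A difference was -0.04 on the log2 scale in fragments on transcripts of at least 600 nt. This list did not stand apart without the filter on low values. Hepatocyte transcription factors as a list had a median of 0.00, with 10 of 19 higher, and HNF4G was at 4.98 and 11.8 TPM (log2 fold change 0.44 in fragments on transcripts of at least 600 nt). Looked up after the values were seen, CEBPA was at 35.6 and 21.1 TPM, the bile acid receptor gene NR1H4 at 40.6 and 25.7 TPM, and HNF4A at 81.8 and 64.5 TPM.

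Cytosolic ribosomal protein mRNAs were slightly lower in 29 of 32 cases, none by 1.5-fold, with a median of -0.12 at percentile 0.41. RPL35, RPL5, RPS2 and RPL32 had log2 fold changes of -0.42, -0.35, -0.31 and -0.24. With random lists matched also on transcript length and GC content this list was at percentile 2.89 and no longer stood apart. Nor did it stand apart in estimated fragments, but members without an estimate, such as RPL35 and RPL32, were left out there. Mitochondrial chaperones and proteases were at percentile 2.37 with a median of -0.12, led by CLPX, HTRA2, TRAP1 and LONP1 at -0.45, -0.43, -0.39 and -0.33, although CLPX was at 0.19 in fragments on transcripts of at least 600 nt. Only 9 of 16 members were lower, and the list did not stand apart under 5 of the 12 alternative settings.

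The other 19 ranked lists stayed within the random range, and 4 of them stood apart under an alternative setting. For these lists, members that went against the direction of the median, and CALR, EDEM1, GADD45A and CDKN1A, were looked up after the values were seen. The CCR4-NOT and PAN2-PAN3 deadenylases and their adaptors, the machinery that removes poly(A) tails, had a median of 0.04 with 11 of 18 higher, and TNKS1BP1 and CNOT4 had log2 fold changes of 0.64 and 0.49. PAN2, a catalytic deadenylase subunit, was at 19.8 and 10.6 TPM, and its log2 fold change was -0.19 in fragments on transcripts of at least 600 nt. Decapping and P-body factors had a median of -0.06, with LSM7 at -0.74 and EDC3 at -0.41. Targets of ATF4, a transcription factor of the amino acid response, were at percentile 96.4 with a median of 0.11, 4 of 26 members at least 1.5-fold higher and none lower by that much. The secreted stress factor GDF15 was at 101 TPM without Dox and 300 with Dox, and PPP1R15A at 16.4 and 37.2. The p53 targets had a median of -0.03 with 11 of 25 higher, and FDXR and TIGAR at -0.67 and -0.58. Its members GDF15, GADD45A and CDKN1A were at 1.55, 0.59 and 0.40. The unfolded protein response list had a median of 0.02, with HERPUD1 at 0.36 beside ERN1. MANF was at 149 TPM without Dox and 73.9 with Dox, and CALR and EDEM1 had log2 fold changes of -0.49 and -0.42.

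Among the metabolic lists within the random range, the median was -0.11 for fatty acid oxidation (SLC25A20 -0.42, ACAA1 -0.33), where PLIN2 and ACSL1, at 0.88 and 0.78, were higher. It was -0.16 for gluconeogenesis, urea cycle and amino acid catabolism (PC -0.48, GLUL -0.43, CPS1 0.56). It was 0.06 for xenobiotic metabolism (CYP1A1 0.91, CYP3A5 0.32), where the closely related GSTA1 and GSTA2 were at -0.68 and -0.65. The fragment ratio of CYP1A1 was 1.46 (interval 1.18 to 1.82), and the median of the xenobiotic members with an estimate was -0.01 in fragments. Complement and coagulation factors had a median of -0.08 (C8G -0.49, F11 -0.48) and stood apart as lower, at percentile 1.83, without the filter on low values. Nuclear-encoded respiratory chain subunits were at -0.07 (UQCRQ -0.51, NDUFV1 -0.51) and the 13 mitochondrially encoded mRNAs at 0.05 (MT-CYB 0.31, MT-ATP8 0.23). Medians were -0.03 for cytosolic heat shock proteins (AHSA1 -0.40, HSPA8 -0.28), 0.04 for replication-dependent histones (H4C15 0.92, H2AC8 0.77, H4C14 -0.63) and 0.09 for common reference genes (PGK1 0.30, YWHAZ 0.29), which stood apart as higher in estimated fragments at percentile 97.9. Of the histones, H4C15 (0.39 and 1.64 TPM) and H2AC8 (1.26 and 2.85 TPM) lay near the filter. The main transcript of H4C15 in one library was listed at 0 in the other. NF-kB and chemokine genes had a median of -0.01 (NFKB2 -0.24, NFKBIE -0.09), while CCL20, ICAM1, TNFAIP3 and NFKBIA were at 1.10, 0.84, 0.56 and 0.43. With a minimum mean TPM of 5, the 7 members left had a median of 0.43 and stood apart as higher at percentile 99.9. Biliary and progenitor markers were at percentile 96.8 with a median of 0.25, and the tight-junction gene CLDN4 had a log2 fold change of 1.27 (fragment ratio 2.64, interval 2.15 to 3.26), and SPP1 was at 0.91 and 1.99 TPM. This list stood apart as higher without the filter on low values (percentile 99.2) and in estimated fragments (also 99.2). Markers of fibroblasts, endothelium and blood were measured for 6 genes, 3 higher and 3 lower, with a median of 0.03, PDGFRB at 4.11 and 7.36 TPM and LYZ at 1583 and 1742 TPM, while ACTA2 was at 61.3 and 36.7 TPM and HBA1 was at 4.14 TPM without Dox and listed at 0 with Dox. ACTA2 and HBA1 were looked up after the values were seen. PDGFRB is another gene whose main transcript in one library was listed at 0 in the other. Its transcripts of at least 600 nt were at 4.11 TPM without Dox and 3.65 with Dox, although their log2 fold change in fragments was 0.71. The homologues of the fly Smaug targets nanos and Hsp83 gave 3 measured genes, too few to rank. HSP90AB1 was at 2433 and 2318 TPM and HSP90AA1 at 336 and 321 TPM.

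**Figure D3:**
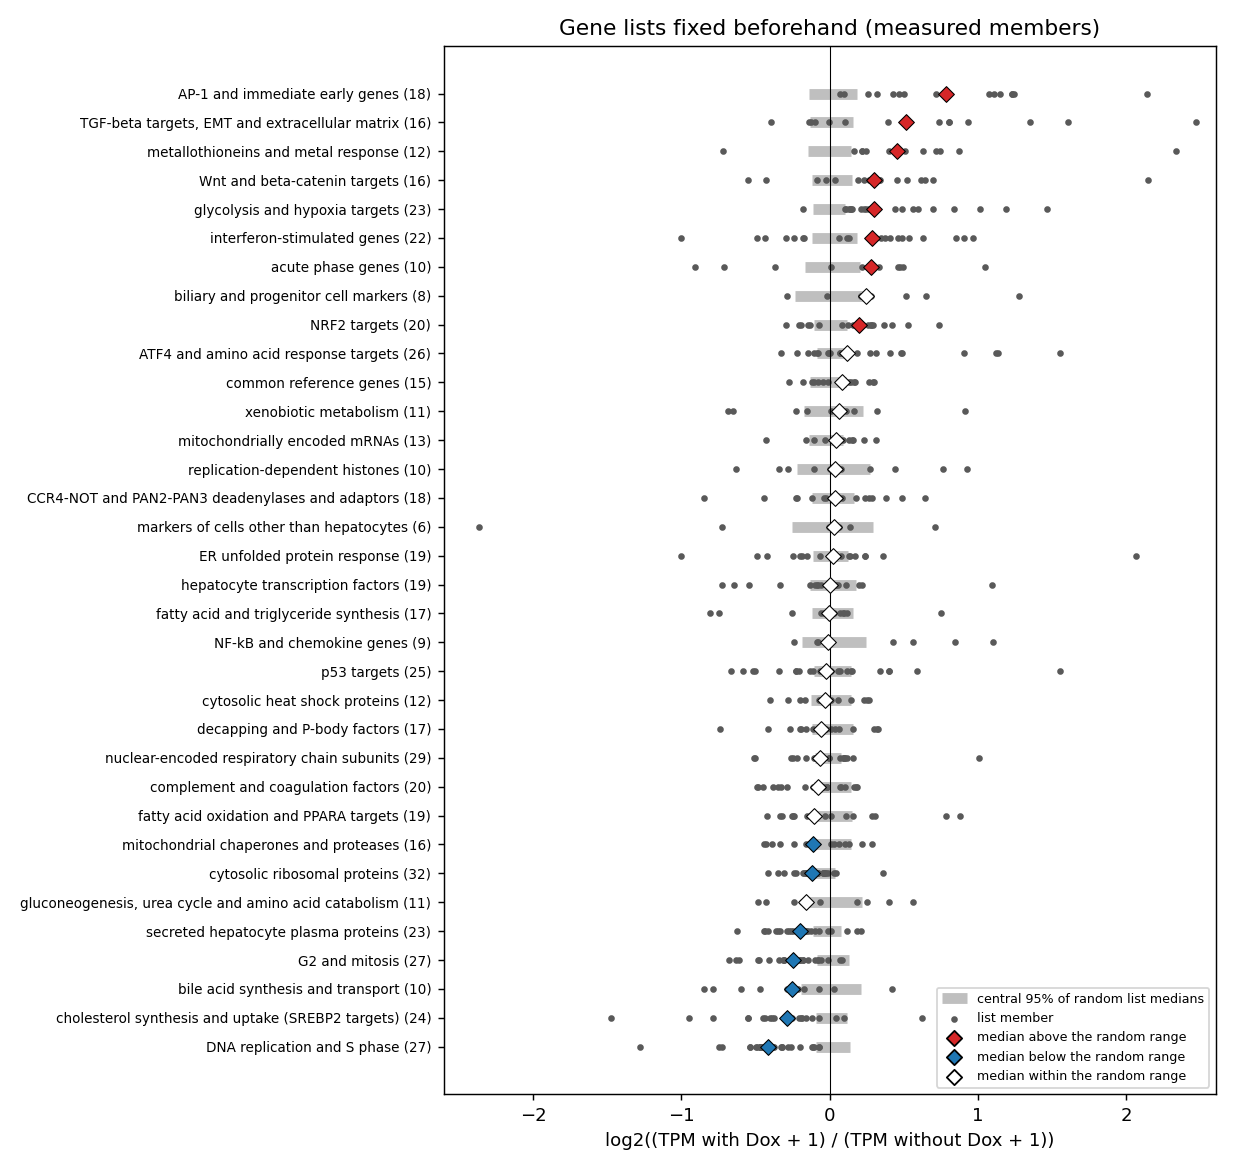
Log2 fold change with against without Dox (horizontal axis, pseudocount of 1 TPM) of the 34 ranked gene lists, with the number of measured members in parentheses, grey dots for members, diamonds for list medians and grey bars for the central 95% of the medians of 10000 random lists. AP-1 and immediate early genes have the highest median at 0.79 and DNA replication and S phase genes the lowest at -0.42.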

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

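The tests of all-or-none genes, of Dox itself and of GC content for ribosomal protein genes were chosen after the result was seen.

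Transcripts without a gene match, which the comparisons do not use, differed more often than matched ones. Of 1044 transcripts without a gene match at a mean TPM of at least 5, 57 were at least 2-fold higher with Dox and 46 at least 2-fold lower, 9.87% of them. Among matched transcripts at the same level the share was 4.61%. Of the 57 higher ones, 15 were listed at 0 without Dox, and 12 of the 46 lower ones were listed at 0 with Dox. Whether fragments moved between copies or the RNA differed was not tested for them.

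For 323 of the 11582 genes compared, the main transcript of one library was listed at 0 in the other, and 131 of them differed by at least 2-fold. SMIM11 and ENSG00000273590, which share 98.8% of the 31-mers of SMIM11, moved in opposite directions, and their summed TPM was 39.7 without Dox and 34.7 with Dox, a ratio of 0.87. This argues against a change of expression for that pair. Of the 323 genes, 11.8% either shared at least 90% of their 31-mers with a transcript of another gene or lay in the major histocompatibility complex region of chromosome 6, where alternate haplotypes exist, against a median of 2.17% in matched random gene sets (upper bound of their central 95%, 4.02%). FLOT1, BAG6 and PPP1R10 lie there, so sharing of fragments between copies may account for those 38 genes, while for the other 285 a move to another isoform or to an unmatched transcript and a real change stay open.

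Immediate early genes were higher and DNA replication genes lower with Dox. Counting error is argued against, since the immediate early median of 0.79 compares with an upper bound of 0.0508 in simulated pairs, and the DNA replication median of -0.42 with a lower bound of -0.03. GC content and transcript length are argued against, since the DNA replication list stayed at percentile 0.0 and the immediate early list at percentile 100 when random lists were matched on both. Dox itself cannot be told apart from SAMD4B, as the design has no library with Dox alone. The ATF4 list, a known response to impaired mitochondrial translation, lay at percentile 96.41, which decides nothing, and a difference in cell density or harvest between the cultures also stays open with 1 library per group.

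Ribosomal protein mRNAs were slightly lower, with a median ratio of 0.92 with over without Dox. Transcript length alone is argued against, since the list stayed at percentile 1.77 with random lists matched on length. With GC content matched too, it was at percentile 2.89. The random lists could draw the list's own members, and finer matching can make these a larger share of the genes drawn from. This test therefore cannot decide whether base composition accounts for part of the small difference. A biological difference stays open and was not tested separately.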

How the results depend on the processing

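The count of genes past a fold depends on the settings more than the gene lists do. Against 188 higher and 112 lower genes, the counts were 296 and 186 with a pseudocount of 0.1 TPM, 55 and 28 with 5 TPM, and 71 and 32 with a minimum mean TPM of 5. They were 616 and 452 at 1.5-fold and 44 and 34 at 4-fold. Protein-coding genes alone gave 74 lower genes. In settings chosen after seeing the data, estimated fragments relative to depth, available for 9786 genes, gave 108 and 46, and removing genes with a main transcript listed at 0 in one library gave 121 and 48, so that 71.6% of the calls were higher against 62.7%. The log2 fold change of SAMD4B was 2.88 in estimated fragments and between 2.34 and 2.46 under the pseudocounts and scalings, against 2.44. No gene named by rule changed sign where it could be estimated. LCN2, OAS1 and CLPX, with under 80% of their TPM on transcripts of at least 600 nt, had log2 fold changes of -0.11, -0.01 and 0.19 in fragments on those transcripts alone, the opposite of their summed TPM. Between 13 and 16 lists stood apart under the 12 alternatives, against 15. The lists gained were complement and coagulation factors and biliary markers without the filter, NF-kB genes at a minimum mean TPM of 5, and biliary markers and common reference genes in estimated fragments. Cytosolic ribosomal proteins were lost in estimated fragments, where several of their members had no estimate. No list that stood apart changed the sign of its median under the pseudocounts, scalings or estimated fragments, but sizes moved. The median of the AP-1 and immediate early genes was 0.96 with a pseudocount of 0.1 TPM and 0.39 with 5 TPM, against 0.79, as a pseudocount shrinks genes with low values, and that of interferon-stimulated genes was 0.12 with 5 TPM. In estimated fragments, the median of the NRF2 targets was 0.11 against 0.20. Of the lists within the random range, 7 changed the sign of medians no larger than 0.06, and the largest change was to -0.24, for markers of other cell types in estimated fragments. The scalings shifted the median of all genes by less than 0.1 on the log2 scale. No paired analysis was possible because each group has 1 library, and leaving out a library was not possible for the same reason. Depth limits single low genes: counting error alone gave up to 39 genes at least 2-fold higher and up to 37 at least 2-fold lower in a simulated pair.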

Other observations

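The reversed-loop control, the matching of hairpin sets on GC content and the rule that leaves the hairpin result open when the control is also low were added after the first hairpin result was seen, and the tests of SRF and of YAP and TAZ target genes were chosen after the named genes were seen but before the values of their lists.

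Cytoskeletal genes that respond to the transcription factor SRF and its cofactors, a group not among the lists fixed beforehand, were higher with Dox in 17 of 19 measured cases. Of the 19, 3 were higher by at least 1.5-fold and 1 was lower by as much. The median was 0.30 on the log2 scale at percentile 100 (none of 10000 random lists reached it). ACTG1 was at 1153 TPM without Dox and 1600 with Dox, TPM4 at 139 and 216, FHL2 at 15.9 and 29.1, and VCL at 33.6 and 48.3, while ACTA2 was lower at 61.3 and 36.7. Only 2 of the 19 genes are also in a list fixed beforehand.

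A hypothesis from CCN1, CCN2, ANKRD1 and F2RL1 is that a wider set of YAP and TAZ target genes was higher with Dox. Among 14 measured genes commonly listed as targets, compiled from general knowledge and without these, 10 were higher, 3 by at least 1.5-fold, with a median of 0.28 at percentile 99.6. AXL was at 1.88 and 6.43 TPM and CRIM1 at 109 and 184, whereas ARHGEF17 was at 10.4 and 7.96. SRF targets moved alike, so the values are consistent with either set of regulators or with both, and they do not show whether SAMD4B, Dox or the state of the culture is the source.

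A further hypothesis is that mRNAs with predicted Smaug recognition hairpins are lower when SAMD4B is induced. Such a hairpin was a CNGG loop with up to 3 further bases on a stem of 5 pairs, with G-U pairs allowed. Among protein-coding genes, the median log2 fold change was 0.02 for 3053 genes without a hairpin, 0.02 for 6074 genes with 1 to 3 and 0.03 for 1985 genes with 4 or more, at percentiles 100, 27.3 and 0.01 of random sets matched on mean TPM and transcript length. The 2778 genes with the most hairpins per kilobase (at least 1.02) had a median of -0.02, at percentile 0.0. The 2780 genes with the most reversed-loop hairpins (GGNC) also had a median of -0.02 at percentile 0.0, so base composition of hairpins in general may produce a difference of this size. With GC content matched as well, the percentiles were 0.22 for the CNGG set and 9.07 for the reversed-loop set, and 99.7, 21.7 and 2.22 for the sets with no hairpin, 1 to 3 and 4 or more. A specific effect stays open.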
